A study of Mus musculus with 9 samples.

How the data were processed

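Lung RNA from 9 female C57BL/6 mice was measured on 9 Affymetrix 3' expression arrays, 1 array per mouse. The labels place 3 mice in each of 3 groups, named for the replication-deficient adenovirus given into the trachea 14 days earlier. The AdV-NULL virus carried no cytokine gene and serves as the control, the AdV-IL4 virus carried mouse IL-4, and the AdV-IL4d2 virus carried mouse IL-4d2, a splice variant of IL-4. Per the labels' protocols, total RNA was extracted with Trizol, 200 ng was primed with an oligo-dT-T7 primer, and biotin-labelled cRNA was made with the 3' IVT Express kit.

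The values deposited by the authors are signal intensities on a linear scale, 1 per probe set and array, for 45101 probe sets. The submitters' processing notes name Affymetrix Expression Console 2.0, MAS5 and GCOS without saying what each did. From the values, each array was scaled by 1 factor, since the 2% trimmed mean was 500.002 on each of the 9 arrays, while the array medians ran from 156 to 171. Detection calls, scanner images and probe sequences were not used here. No depth applies to arrays, so the number of arrays per group limits the precision. MAS5 scaling sets the typical signal of every array to the same level, so a change shared by most genes is not visible in these values, and low signals are noisy.

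Gene names came from the platform annotation table. It lists 35890 of the probe sets, 34958 with 1 gene symbol and 932 with several, and the other 9211 are unnamed here. Of the symbols, 34754 matched a current gene record by Entrez identifier, and 0 had to be renamed. No gene was named from a probe set with several symbols. Where a gene had several tested probe sets, as 5047 genes did, the one with the highest mean log2 signal over the 9 arrays stood for it.

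Signals were transformed to log2(signal + 16). Probe sets above the median of their own array on at least 3 of 9 arrays were tested, and 64 control probe sets were left out, which left 23824 probe sets and 11984 genes with a single symbol. All 9 arrays entered 1 linear model without covariates, fitted with lmFit and eBayes (trend) of limma 3.58.1 in R 4.3.3, with 6 residual degrees of freedom. The 3 contrasts were IL-4 against control virus, IL-4d2 against control virus and IL-4 against IL-4d2, the last of which tests whether the effects of the cytokine forms differ. A moderated F test covered the 3 groups together. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast with a threshold of 0.05. Fold changes are ratios on the log2(signal + 16) scale, which understates changes of dim probe sets. Errors after log2 differences are standard errors of the fit, and errors after signals are SDs over the 3 arrays of a group.

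Gene lists of cell types, pathways and tissues, 32 in all, were written before the data were examined, together with the design, the alternatives and the rule for named genes. Of their 596 written members, 437 entered the tests, and 50 had no match in the gene table and were not analysed here. Members were counted by the limma calls, adjusted over all probe sets and adjusted over the list alone. Shifts of whole lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes, adjusted over the 32 lists. The alternative with an estimated correlation allows for genes of a list that vary together between mice. It was applied to each list, and its adjusted p stands beside each list call. A further 11 lists, adjusted only among themselves, and the scaling to control transcripts were chosen after the data were seen. The same holds for the fits without control mouse 1 and IL-4 mouse 2, whose muscle signals stood apart.

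The rule for named genes took, per comparison, the 8 with the largest increase and the 8 with the largest decrease among called genes whose groups did not overlap. Up to 4 called members of each list with the largest changes were taken too, or the 2 with the highest signal where fewer than 2 were called, along with Il4, Il4ra, Stat6 and the Gapdh and Actb control probe sets. The text does not give the value of every gene that the rule took. Some without a value lost their call in most fits with 1 array left out, such as Ptgs2 and Lat with IL-4 (8 of 9 fits each). Others, such as Vwf and Erg with IL-4, kept it in each fit. The genes with values are therefore no fair sample of how stable the calls were. Unnamed loci, RIKEN and similar symbols and immunoglobulin or T cell receptor segments were left out of the largest changes. List members that did not pass the threshold and are not named in the text are given only as counts, a choice made after their values were seen. Genes named outside the rule were chosen after their values were seen. They are members of the added lists, or genes of 1 comparison whose values are also given for another.

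Both comparisons against the control virus share the same 3 control arrays. Overlaps and correlations between them therefore stand beside values from 50 simulations of unchanged groups with shared control arrays. Overlaps also stand beside that of independent lists. With 3 control arrays, no 2 sets of at least 2 separate controls can be made.

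The test was run on simulated data for IL-4 against control virus, over 23824 probe sets with 200 changed in each of 10 simulations. It recovered 26.5% of probe sets changed 1.41-fold, 81.1% of those changed 2-fold and 99.0% of those changed 4-fold, and 90 of 1531 calls were false. In 10 simulations of the list test over 11984 genes, camera at the preset correlation found 10 of 10 lists of 20 genes shifted by 0.5 on the log2 scale, and 2 of 10 unshifted lists. These counts are at an unadjusted p under 0.05. Simulated genes varied independently, while the estimated correlation within the real lists reached 0.83. The simulation therefore cannot show how camera behaves on lists whose genes vary together.

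The alternatives covered other pseudocounts, filters, normalizations between arrays, variance settings, array weights, thresholds and probe sets, fits of only the compared groups, a block on the mouse number, other list tests, and each array left out in turn. Array quality was compared with exact permutation tests, for which 3 arrays against 3 give a smallest p of 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.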

Results

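The arrays measured RNA of whole lungs taken 14 days after infection from 9 mice aged 14 weeks, 3 per virus. IL-4 is the cytokine that drives type 2 immune responses, and IL-4d2 is a splice variant of it. The comparisons ask what each form changed in the lung relative to a virus without a cytokine gene, and where the forms differed in the inflammation they set off. The control virus arrays give the background for every value. Signals are MAS5 intensities, with medians between 156 and 171 on the 9 arrays.

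Il4 itself had a signal of 43.5 ± 27.9 in control mice, 338 ± 39.1 in IL-4 mice and 872 ± 343 in IL-4d2 mice (SD, n = 3 each). It rose 6.43-fold with IL-4 (log2 difference 2.69 ± 0.35, limma adjusted p = 0.000836) and 15.3-fold with IL-4d2 (3.93 ± 0.35, adjusted p = 7.69e-05). The log2 difference of −1.25 ± 0.35 between IL-4 and IL-4d2 did not pass the test (adjusted p = 0.104). The control signals lay near those of trpn, a bacterial transcript used as a negative control on such arrays, which reached 55.8 on 1 control array. Against that level Il4 was at least 4.91-fold higher with IL-4 and at least 11.7-fold higher with IL-4d2. The part of the transcript that this probe set reads is not given in the sources used here, so its signal need not count both vector transcripts alike. Il4ra, a chain of the IL-4 receptor, and Stat6, the transcription factor through which it signals, did not pass the test in any of the 3 comparisons. Their log2 differences were 0.15 and 0.13 with IL-4 (adjusted p = 0.488 and 0.354) and 0.27 and 0.17 with IL-4d2 (0.363 and 0.357).

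**Figure D1:**
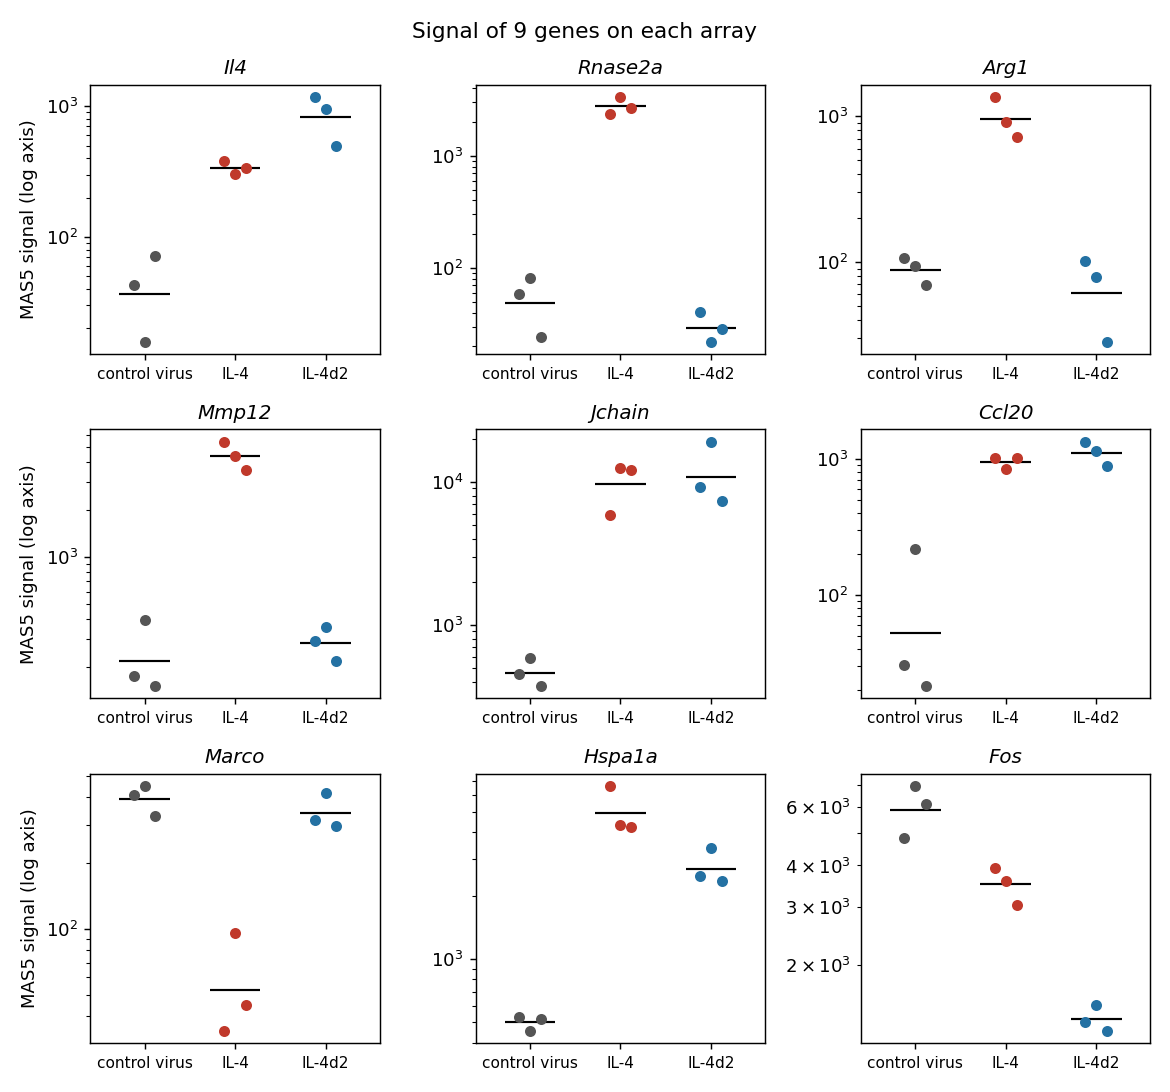
MAS5 signal (log axis) of 9 genes on each of the 9 arrays; each point is 1 mouse, coloured by virus, and each bar is the geometric mean of 3 mice. Rnase2a, Arg1 and Mmp12 were high on the IL-4 arrays, Jchain and Ccl20 were high on the arrays of both cytokine viruses, and Fos was lowest on the IL-4d2 arrays.

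With IL-4, the lists of alternatively activated macrophages, type 2 chemokines, antibody-producing cells, antigen presentation and extracellular matrix held more genes that rose than fell against control virus, and those of smooth muscle, club cells and heart muscle held more that fell. With an estimated correlation camera called 0 of the 32 lists (lowest adjusted p = 0.151), against 23 at the preset one. Rnase2a, of the gene family named eosinophil-associated ribonucleases, showed the largest increase, from 54.7 ± 28.6 in control mice to 2776 ± 495 in IL-4 mice (SD, n = 3). That was 41.7-fold (log2 difference 5.38 ± 0.30, adjusted p = 2.24e-06), from a control signal below the array median on all 3 control arrays, and at least 38.5-fold above the brightest trpn signal. Mmp12, the macrophage elastase, rose 18.8-fold (adjusted p = 8.50e-06), and the arginase Arg1, an enzyme of alternatively activated macrophages, rose 9.33-fold (adjusted p = 0.000192). Slc26a4, the anion exchanger pendrin of mucus-producing epithelium, rose 20.4-fold (adjusted p = 0.000140), a log2 difference of 4.35 that was 5.01 without control mouse 2.

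Of the 20 tested genes of alternatively activated macrophages, 15 rose (17 adjusted over the list alone, with 1 fall). The list shifted upward with a median log2 difference of 0.73 (camera adjusted p = 1.36e-11, adjusted p = 0.151 with an estimated correlation). Chil4, a chitinase-like protein, rose 10.5-fold from 928 ± 798 to 10062 ± 9469, a spread as wide as the mean, and its log2 difference of 3.39 was 4.06 without control mouse 2, 2.73 without control mouse 3 and 2.66 without IL-4 mouse 1. Clec7a, the beta-glucan receptor, rose 3.31-fold. All 5 tested type 2 chemokines rose (5 adjusted over the list alone), by a median of 1.94 (camera adjusted p = 9.30e-07, adjusted p = 0.159 with an estimated correlation). Among them Ccl9 rose 5.73-fold, Ccl8 4.32-fold, Ccl6 3.83-fold and Ccl17, a ligand of the Th2 cell receptor Ccr4, 2.84-fold. Of 6 type 2 cytokines and receptors, Il4 and Il33 rose, Il33 by 2.55-fold (2 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.258 with an estimated correlation). Il4 is the gene that the virus carried, so the list call in part reads the vector. The list had a mean of 0.64 and a median of 0.14, and was not tested without Il4. Of 14 goblet cell and mucus genes, Slc26a4 and the lectin Itln1 rose (5 adjusted over the list alone, camera adjusted p = 0.00705, adjusted p = 0.457 with an estimated correlation). The Itln1 call, with a log2 difference of 3.74, was lost without control mouse 1 (3.44), control mouse 3 (3.04), IL-4 mouse 1 (2.83) or IL-4 mouse 3 (3.58), and the value was 4.75 without control mouse 2 and 4.82 without IL-4 mouse 2.

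Lymphocyte genes rose with IL-4 as well. Jchain, which joins the units of secreted IgM and IgA, went from 471 ± 109 to 10178 ± 3706, a 20.2-fold rise (log2 difference 4.33 ± 0.34, adjusted p = 2.07e-05). Of 11 plasma cell genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), including Ighm at 5.89-fold, Irf4 at 4.74-fold and Mzb1 at 3.19-fold (camera adjusted p = 0.000300, adjusted p = 0.251 with an estimated correlation). Of 18 B cell genes, 11 rose (14 adjusted over the list alone), including Pou2af1 at 2.72-fold, Spib at 2.66-fold and Cd72 at 2.25-fold (camera adjusted p = 2.16e-09, adjusted p = 0.159 with an estimated correlation). Of 15 T cell genes, 3 rose (6 adjusted over the list alone), among them the costimulatory receptors Ctla4 at 2.84-fold and Icos at 2.12-fold (camera adjusted p = 0.00100, adjusted p = 0.315 with an estimated correlation). Ccl20, which attracts Ccr6-bearing lymphocytes and dendritic cells, rose 13.1-fold (adjusted p = 0.00101) from 89.8 ± 111 to 959 ± 104, a log2 difference of 3.72 that was 4.55 without control mouse 2.

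Antigen presentation genes rose with them. Of 11 MHC class II presentation genes, 10 rose (11 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 1.79e-10, adjusted p = 0.159 with an estimated correlation). The cathepsin Ctss, which trims the invariant chain, rose 3.36-fold and H2-Ab1 2.14-fold. Of 13 dendritic cell genes, 6 rose (7 adjusted over the list alone), including Itgax at 3.01-fold and Cd83 at 2.97-fold (camera adjusted p = 6.92e-06, adjusted p = 0.159 with an estimated correlation). Of 22 interferon-gamma and Th1 genes, 10 rose (14 adjusted over the list alone), including the Cxcr3 ligands Cxcl9 at 6.78-fold and Cxcl10 at 2.85-fold (camera adjusted p = 9.07e-08, adjusted p = 0.251 with an estimated correlation). The log2 difference of Cxcl9 was 2.76, and 3.51 without control mouse 2. Type I interferon-induced genes rose in 4 of 23 cases (4 adjusted over the list alone), with Oas2 at 1.82-fold and Oas1a at 1.80-fold (camera adjusted p = 0.00938, adjusted p = 0.497 with an estimated correlation).

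Macrophage and monocyte genes moved both ways, with 9 of 20 higher and 2 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.000791, adjusted p = 0.377 with an estimated correlation). Gpnmb, a lysosomal glycoprotein, rose 5.40-fold. The scavenger receptor Marco was 5.85-fold lower and the fatty acid binding protein Fabp1 5.28-fold lower. Of 16 lipid handling genes, 5 rose (8 adjusted over the list alone, with 1 fall), including the scavenger receptor Msr1 at 2.34-fold and the lipid droplet protein Plin2 at 1.75-fold (camera adjusted p = 0.00141, adjusted p = 0.320 with an estimated correlation). In the neutrophil list of 6, the calgranulins S100a9 and S100a8 were 4.98-fold and 3.91-fold lower, while 1 gene rose (1 and 3 adjusted over the list alone, camera adjusted p = 0.0780). Of the 13 eosinophil genes written, only 2 passed the filter and were tested. Both lay below control, and Adgre4 was called, 2.17-fold lower (2 adjusted over the list alone, camera adjusted p = 0.0397, adjusted p = 0.251 with an estimated correlation). So few genes cannot show whether eosinophils changed. Rnase2a, which rose, was not among them, and its family name does not settle which cells made it. Of 14 proinflammatory cytokines and chemokines, 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0780), and Ccl3 rose 3.72-fold. Cell cycle genes rose in 4 of 22 cases (5 adjusted over the list alone, camera adjusted p = 0.000300, adjusted p = 0.377 with an estimated correlation), including Cdca8 at 1.86-fold. With 1 array left out, Cdca8 kept its call in each fit, while Mcm5, Top2a and Mki67 lost theirs in 8, 4 and 3 of 9 fits.

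Extracellular matrix and fibrosis genes rose in 14 of 23 cases and fell in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 2.04e-10, adjusted p = 0.159 with an estimated correlation). Eln, which encodes elastin, rose 4.95-fold (log2 difference 2.31 ± 0.14, adjusted p = 3.28e-06). Col1a1, a chain of type I collagen, rose 2.44-fold on its brighter probe set, while its next probe set gave a log2 difference of −0.15. Smooth muscle and fibroblast genes fell in 9 of 19 cases and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.000257, adjusted p = 0.159 with an estimated correlation). The smooth muscle myosin Myh11 was 3.75-fold lower and the proteoglycan Dcn 2.23-fold lower. Car3, a carbonic anhydrase of muscle and fat, showed the largest decrease, 16.1-fold (log2 difference −4.00 ± 0.85, adjusted p = 0.0118), and without control mouse 1 and IL-4 mouse 2 together it lost its call at −2.44. It was −3.39 without control mouse 1, −4.62 without control mouse 3 and −3.06 without IL-4 mouse 2. Striated muscle and fat genes were lower on the same arrays. Of 14 heart muscle genes, 9 fell (13 adjusted over the list alone), with a median of −2.16 (camera adjusted p = 1.05e-06, adjusted p = 0.320 with an estimated correlation). The cardiac actin Actc1 was 4.86-fold lower. The skeletal muscle mean was 13.1 on the array of control mouse 1, against 10.1 and 8.55 for the other control mice, and the heart mean was 7.28 on that of IL-4 mouse 2, against 8.95 and 9.04. The skeletal muscle genes Acta1, Mylpf, Mb and Tnnt3 were 11.9-fold, 11.6-fold, 11.4-fold and 10.6-fold lower, and none of these calls was stable. Acta1 lost its call without control mouse 2 (−3.66) or IL-4 mouse 1 (−3.85), 2 (−3.28) or 3 (−3.58), and was −2.14 without control mouse 1. Mylpf lost it without control mouse 1 (−2.02) or 2 (−3.86), IL-4 mouse 1 (−3.61), 2 (−3.11) or 3 (−3.89), or any IL-4d2 mouse (−3.54). Mb lost it without control mouse 1 (−2.46) or 2 (−3.74), IL-4 mouse 2 (−2.57) or 3 (−3.91), or IL-4d2 mouse 1 or 3 (−3.52). Tnnt3 lost it without control mouse 1 (−1.96) or 2 (−3.70), IL-4 mouse 1 (−3.20), 2 (−3.34) or 3 (−3.68), or IL-4d2 mouse 1 or 3 (−3.40). Without control mouse 3 the 4 values were −4.90, −4.73, −4.35 and −4.55. Of 4 tested genes of fat, thymus and thyroid, 3 fell (3 adjusted over the list alone, camera adjusted p = 0.00838, adjusted p = 0.162 with an estimated correlation), among them the fat droplet gene Cidec, 5.30-fold lower.

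Club, ciliated and alveolar type 1 cell lists shifted downward by small amounts, and the alveolar type 2 list shifted upward. Of 16 club cell genes, 5 fell (5 adjusted over the list alone), including Cldn10, 1.89-fold lower, and Cyp4b1, 1.60-fold lower (camera adjusted p = 0.00223, adjusted p = 0.210 with an estimated correlation). Of 19 ciliated cell genes, 3 fell (12 adjusted over the list alone), with Tppp3 1.79-fold lower (camera adjusted p = 6.23e-05, adjusted p = 0.422 with an estimated correlation). With 1 array left out, Tppp3 kept its call in each fit, while Tekt4 and Ccdc153 lost theirs in 5 and 8 of 9 fits. Of 15 alveolar type 1 genes, 4 fell (4 adjusted over the list alone), with Vegfa lower by a log2 difference of −0.58 (camera adjusted p = 0.0105, adjusted p = 0.477 with an estimated correlation), while 4 of 14 alveolar type 2 genes rose (4 adjusted over the list alone, camera adjusted p = 0.00180, adjusted p = 0.422 with an estimated correlation). None of the alveolar type 2 calls was stable: Muc1, Lgi3, Slc34a2 and Sftpd lost theirs in 7, 6, 5 and 2 of 9 fits with 1 array left out. Of the type 1 calls, Akap5 and Aqp5 were lost in 6 and 4 fits, while Vegfa and Clic5 held in each. Endothelial genes went both ways, with 2 higher and 5 lower of 21 (3 and 6 adjusted over the list alone, camera adjusted p = 0.0771), among them the receptor Kdr, 1.62-fold lower. In the lymphoid tissue, cytotoxic cell and red blood cell lists, limma called 0 of 7, 0 of 11 and 0 of 4 genes, with 2, 1 and 1 at an unadjusted p under 0.05 and 2, 0 and 0 adjusted over the list alone, and neither camera nor fry called those lists. The mast cell and housekeeping lists, with 1 of 3 lower and 2 of 12 higher (1 and 2 adjusted over the list alone), had camera adjusted p = 0.895 and 0.340.

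limma called 2546 of 23824 probe sets for IL-4 against control virus at an adjusted p under 0.05, 1335 higher and 1211 lower, and 453 of them changed at least 2-fold. Groups did not overlap in 29.2% of the probe sets, where chance gives 10%. The count was 1313 without control mouse 1, 1696 without control mouse 3 and 1068 without both control mouse 1 and IL-4 mouse 2. Without those 2 arrays 10 alternatively activated macrophage genes, 4 type 2 chemokines, 6 B cell genes, 4 plasma cell genes, 7 MHC class II genes and 11 matrix genes rose, and 1 heart muscle gene and 6 smooth muscle and fibroblast genes fell. Calls went from 10 to 4 for interferon-gamma and Th1 genes, 9 to 5 for macrophage genes that rose, 6 to 4 for dendritic cell, 5 to 2 for lipid handling, 3 to 2 for T cell, 4 to 3 for type I interferon, 2 to 1 for proinflammatory genes that rose, 3 to 1 for ciliated cell, 3 to 1 for fat, thymus and thyroid, and 5 to 4 for club cell genes. limma called none of the cell cycle, alveolar type 2, housekeeping and mast cell genes and neither endothelial gene that rose, while 4 goblet cell genes rose instead of 2. The 3'/5' signal ratio of Gapdh, which grows as RNA is degraded, was 1.71 ± 0.143 on IL-4 and 1.28 ± 0.284 on control arrays (exact p = 0.1, the smallest possible). That of Actb was 3.23 ± 0.486 and 2.65 ± 0.324 (exact p = 0.3), and the 18S ribosomal RNA signal was lower by a log2 difference of −0.68 (exact p = 0.1). Bacterial control transcripts added during labelling and hybridisation were brighter on IL-4 arrays, and scaling to the hybridisation or the poly-A controls moved the median of all genes by −0.43 or −0.77, to 295 higher and 7156 lower or to 152 higher and 17971 lower. Every direction given here, list directions included, is relative to that shift.

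**Figure D2:**
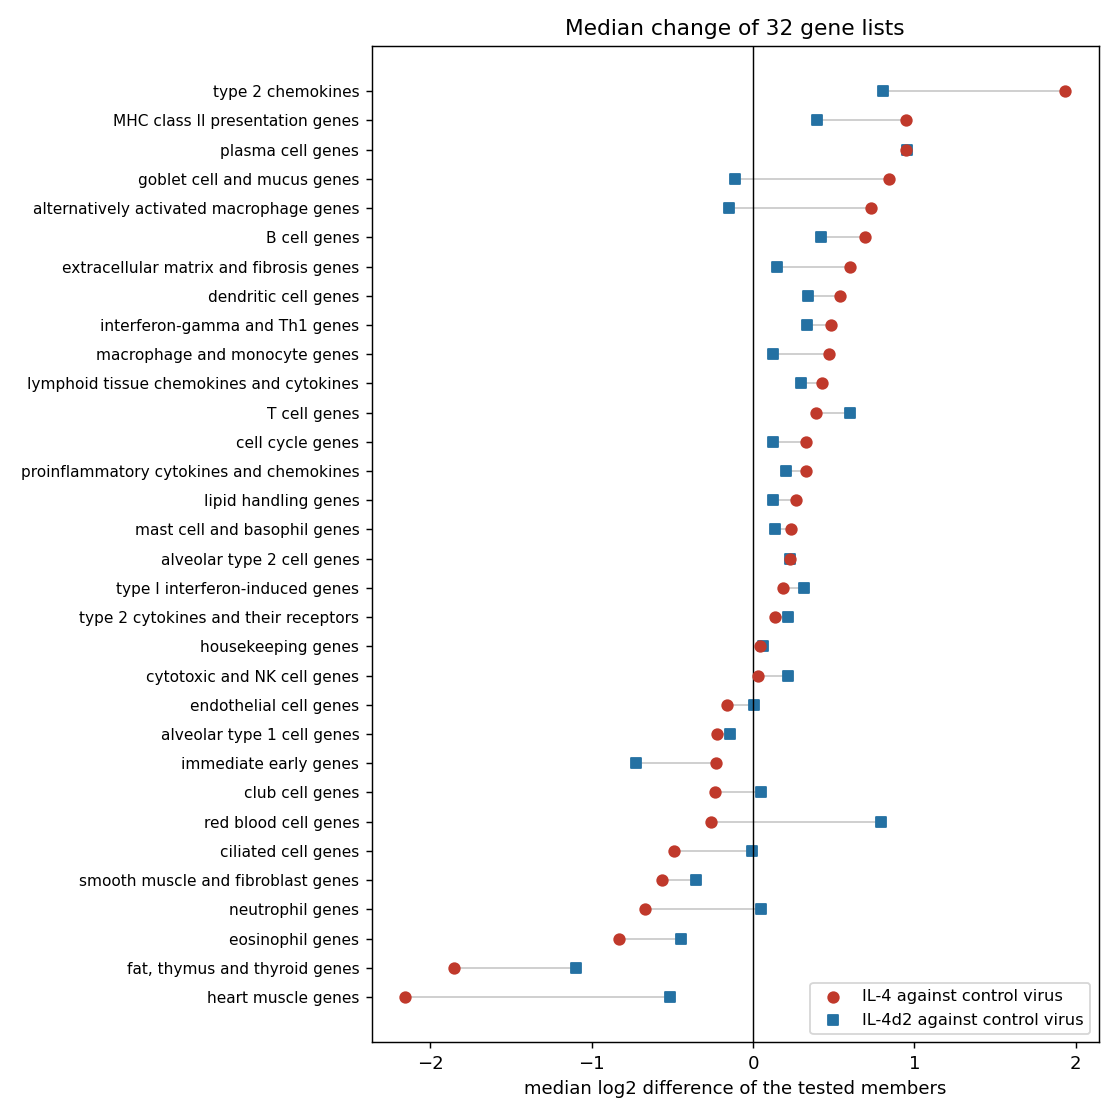
Median log2 difference (horizontal axis) of the tested members of 32 gene lists, with IL-4 (circles) and with IL-4d2 (squares) against control virus, on the arrays as scaled by the authors. The median of the alternatively activated macrophage list was 0.73 with IL-4 and −0.15 with IL-4d2, and that of the plasma cell list was 0.95 with both.

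With IL-4d2, the lists of plasma cells and B cells held more genes that rose than fell against control virus, that of immediate early genes held more that fell, and the chemokine Ccl20 and the heat shock genes Hspa1a and Hspa1b rose. With an estimated correlation camera called 0 of the 32 lists (lowest adjusted p = 0.251), against 21 at the preset one. Jchain rose 22.8-fold, from 471 ± 109 to 11864 ± 6319 (SD, n = 3; log2 difference 4.51 ± 0.34, adjusted p = 2.12e-05). Ccl20 rose 15.2-fold (adjusted p = 0.00171) and Cxcl9 7.16-fold (adjusted p = 0.0148), log2 differences of 3.92 and 2.84 that were 4.76 and 3.59 without control mouse 2. The inducible heat shock proteins Hspa1b and Hspa1a rose 6.27-fold and 5.23-fold, and Hsph1, a co-chaperone of the same family, rose 4.01-fold (adjusted p = 3.20e-05). Hspa1a and Hspa1b were also called higher with IL-4. The Hspa1a signal was 6643, 4333 and 4234 on the IL-4 arrays, against 2479, 3372 and 2341 on the IL-4d2 arrays. limma called that difference between the forms, a call lost in 3 of the 9 fits with 1 array left out. Egr1 and Fos, transcription factors switched on within minutes by growth and stress signals, were 7.75-fold and 4.27-fold lower (adjusted p = 4.11e-05 and 1.21e-05).

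Of 11 plasma cell genes, 3 rose (7 adjusted over the list alone, with 2 falls), namely Jchain, Ighm at 6.48-fold and Mzb1 (log2 difference 1.85) (camera adjusted p = 6.07e-06, adjusted p = 0.251 with an estimated correlation). Of 18 B cell genes, 4 rose (11 adjusted over the list alone), including Spib at 3.40-fold, Pou2af1 at 2.52-fold and Cd72 at 2.37-fold (camera adjusted p = 1.14e-08, adjusted p = 0.251 with an estimated correlation). Of 15 T cell genes, 3 rose (8 adjusted over the list alone), with Ctla4 at 2.74-fold (camera adjusted p = 2.41e-07, adjusted p = 0.251 with an estimated correlation). The Ctla4 call, at a log2 difference of 1.45, was lost without IL-4d2 mouse 3 (1.38). Of 22 interferon-gamma and Th1 genes, 3 rose (9 adjusted over the list alone, camera adjusted p = 9.21e-06, adjusted p = 0.311 with an estimated correlation). The Cxcl9 call, at a log2 difference of 2.84, was lost without control mouse 1 (2.64) or without IL-4d2 mouse 1 (2.82), 2 (2.88) or 3 (2.83). Of 23 type I interferon-induced genes, 1 rose (9 adjusted over the list alone, with 1 fall, camera adjusted p = 6.09e-05, adjusted p = 0.324 with an estimated correlation). Of 11 MHC class II genes, 3 rose (7 adjusted over the list alone, camera adjusted p = 1.21e-06, adjusted p = 0.251 with an estimated correlation), and 1 of 13 dendritic cell genes did (3 adjusted over the list alone, camera adjusted p = 0.0179, adjusted p = 0.311 with an estimated correlation). With 1 array left out, the MHC class II calls H2-Ab1, Ifi30 and H2-Eb1 were lost in 8, 5 and 4 of 9 fits. The dendritic cell call, Itgae, was lost in 5, and the type I interferon call, Oas1a, in 4. Cxcl10 and Cxcr3 lost theirs in 5 and 7, the T cell genes Cd3g and Lat in 5 each. So did the B cell gene Ms4a1 in 6 and the matrix gene Col5a2 in 7. Eln rose 2.33-fold and the crosslinking enzyme Lox also rose (adjusted p = 0.000600) among the 3 of 23 matrix genes that rose (7 adjusted over the list alone, with 1 fall, camera adjusted p = 0.000726, adjusted p = 0.311 with an estimated correlation). The macrophage gene Ms4a7 rose 3.14-fold, as the 1 call of that list of 20 (4 adjusted over the list alone, with 1 fall, camera adjusted p = 0.0835).

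The immediate early list of 17 held 10 genes that fell and 2 that rose (10 and 2 adjusted over the list alone, camera adjusted p = 1.14e-08, adjusted p = 0.251 with an estimated correlation). The 2 were Hspa1a and Hspa1b, which are heat shock proteins, and the 10 included Nr4a1, 3.34-fold lower, Ccn1, 3.16-fold lower, and Dusp1, 2.24-fold lower. The Ccn1 fold is that of its brightest probe set, and 2 of its other probe sets gave log2 differences of −3.22 and −3.51. With IL-4, 8 of the 17 fell and 4 rose (8 and 4 adjusted over the list alone), the list median was −0.23 and its mean 0.05, and camera gave adjusted p = 0.182. Cirbp, a cold-inducible RNA-binding protein, was 2.78-fold lower with IL-4d2 and 3.40-fold lower with IL-4. Rgs2, a brake on G protein signalling, was 2.41-fold lower with IL-4d2. In the red blood cell list of 4, Alas2 and Bpgm were called higher with IL-4d2 (3 adjusted over the list alone, camera adjusted p = 0.000726, adjusted p = 0.251 with an estimated correlation). Alas2, at 1.31, lost its call without control mouse 1 (1.27), control mouse 2 (1.10), IL-4d2 mouse 1 (1.22) or IL-4d2 mouse 3 (1.12), and Bpgm, at 0.68, without any control mouse (0.66, 0.65 and 0.73), IL-4 mouse 3 (0.68), IL-4d2 mouse 1 (0.70) or IL-4d2 mouse 3 (0.52).

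Of the genes that rose with IL-4, 5 that did not pass the test with IL-4d2 are given here. The log2 difference was −0.54 for Rnase2a (adjusted p = 0.456), −0.41 for Arg1 (0.643), −1.21 for Chil4 (0.477), 0.34 for Mmp12 (0.648) and 1.02 for Slc26a4 (0.315). In the alternatively activated macrophage list, 2 of 20 fell (2 adjusted over the list alone), the macrophage lectin Mgl2 and the arginine transporter Slc7a2 (camera adjusted p = 0.0179, adjusted p = 0.311 with an estimated correlation). With 1 array left out, the Mgl2 call, at −0.56, held in the fit without IL-4 mouse 1 and was lost without any of the other 8 arrays (−0.59 to −0.53). The Slc7a2 call, at −0.44, held without IL-4 mouse 1 or 2 and was lost without any of the other 7 (−0.49 to −0.40). limma called 0 of 5 type 2 chemokines, with 4 at an unadjusted p under 0.05 and 4 adjusted over the list alone, and camera called the list (adjusted p = 0.00127, adjusted p = 0.311 with an estimated correlation). Some lists moved with few or no single calls. limma called 0 genes of the cytotoxic (11), lymphoid tissue (7), cell cycle (22), alveolar type 2 (14), alveolar type 1 (15), smooth muscle and fibroblast (19) and fat, thymus and thyroid (4) lists, with 2, 4, 5, 6, 2, 8 and 4 at an unadjusted p under 0.05 and 1, 3, 2, 0, 1, 7 and 4 adjusted over the list alone. camera put the first 4 upward (adjusted p = 0.0215, 0.0207, 0.00914 and 9.68e-05) and the last 3 downward (adjusted p = 0.0215, 0.000291 and 0.00127). None kept its call (adjusted p = 0.311, 0.311, 0.535, 0.311, 0.578, 0.251 and 0.251 with an estimated correlation). Il4 and Il33 rose among the 6 type 2 cytokines and receptors (2 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.251 with an estimated correlation). Since a form of Il4 was carried by the virus, this list call in part reads the vector. Its mean was 0.73 and its median 0.22, and no test left Il4 out. The Il33 call, at 0.58, was lost without control mouse 1 (0.49), control mouse 3 (0.53), IL-4 mouse 3 (0.58) or IL-4d2 mouse 1 (0.50), 2 (0.61) or 3 (0.62). camera did not call the goblet cell, eosinophil, mast cell, neutrophil, lipid handling, proinflammatory, ciliated, club, endothelial and housekeeping lists (adjusted p from 0.105 to 0.998). The neutrophil median was 0.05 where camera put the list downward, and the club cell median was 0.05 with a mean of −0.01.

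The 14 heart muscle genes, of which limma called 0, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone, lay lower by a median of −0.52 (camera adjusted p = 0.0202, adjusted p = 0.641 with an estimated correlation). The skeletal muscle mean stood 2.44 below that of the control arrays (exact p = 0.1, the smallest possible), and 1.18 below without control mouse 1.

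For IL-4d2 against control virus, limma called 314 probe sets, 221 higher and 93 lower, and 110 of them changed at least 2-fold. Groups did not overlap in 21.3% of the probe sets, where chance gives 10%. The count was 187, 163 or 156 without IL-4d2 mouse 1, 2 or 3, 200 without control mouse 1, 189 without control mouse 3, and 593 with arrays weighted by quality. Without control mouse 1 and IL-4 mouse 2 together, calls went from 3 to 1 for MHC class II genes, 3 to 1 for T cell genes, 4 to 3 for B cell genes and 3 to 2 for matrix genes that rose. limma then called none of the interferon-gamma and Th1, type I interferon, dendritic cell, red blood cell and alternatively activated macrophage genes, and of the type 2 cytokines 1. Scaling to the hybridisation or the poly-A controls moved the median of all genes by 0.08 or 0.27 and the calls to 245 higher and 63 lower or to 469 higher and 50 lower.

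Of the 314 probe sets called with IL-4d2, 265 were also called with IL-4 in the same direction, 198 higher in both and 67 lower in both, and 2 were called in opposite directions. Unchanged groups simulated with shared control arrays had on average 0.04 shared calls in either direction. Groups without a change give almost no calls, so that value is no baseline for the 198 and 67 shared calls. How many calls the shared controls add when a group does change was not simulated. Independent lists of these lengths would share 12.4 and 4.73, which leaves the shared controls out of account. Across probe sets, which are not independent replicates, the log2 differences of the 2 cytokine groups correlated at r = 0.686, against 0.499 in the simulation. Their covariance was 0.0897 against 0.0174, a difference of 0.0723. Part of the overlap beyond that of independent lists may come from the shared controls. Without IL-4d2 mouse 1, 2 or 3 the shared calls numbered 161, 143 or 145, and without control mouse 3 they numbered 169. Of the 265 shared calls, 13 also differed between the cytokine forms, and of 47 probe sets called with IL-4d2 alone, 13 did. Of 2279 probe sets called with IL-4 alone, 324 did.

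In the direct comparison, alternatively activated macrophage genes, among them Chil4, and the elastase Mmp12 were higher with IL-4 than with IL-4d2, and the calgranulin S100a9, Marco and Pon1 were lower. Rnase2a was at 2776 ± 495 against 30.4 ± 9.43 (SD, n = 3; 60.4-fold, log2 difference 5.92 ± 0.30, adjusted p = 3.53e-06). Its IL-4d2 signal lay below the brightest trpn signal, so the floor allows only a statement of at least 38.5-fold. Chil4 was 24.2-fold higher (adjusted p = 0.00748), a log2 difference of 4.60 that was 3.86 without IL-4 mouse 1. Mmp12 was 14.8-fold higher (0.000123), Arg1 12.4-fold (0.000437) and Fbp1, an enzyme of gluconeogenesis, 7.26-fold (0.000259). S100a9 was 5.46-fold lower (adjusted p = 0.00521), Marco 5.08-fold lower (0.00196) and Pon1, a paraoxonase, 3.52-fold lower (0.000374).

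Of 20 alternatively activated macrophage genes, 14 were higher with IL-4 (16 adjusted over the list alone), and the list median was 0.95 (camera adjusted p = 6.49e-23). It was the 1 list of the 96 list tests that kept its call with an estimated correlation (adjusted p = 0.0270). Clec7a was 2.96-fold higher. Of 5 type 2 chemokines, 3 were higher (3 adjusted over the list alone, camera adjusted p = 1.79e-05, adjusted p = 0.264 with an estimated correlation), with Ccl17 at 3.25-fold. Of 23 matrix genes, 6 were higher (11 adjusted over the list alone, with 1 lower, camera adjusted p = 9.32e-09, adjusted p = 0.264 with an estimated correlation), among them the glycoprotein Tnc at 2.27-fold and Eln at 2.12-fold. Col1a1 was 1.92-fold higher on its brighter probe set and its next probe set gave −0.17. Of 13 dendritic cell genes, 3 were higher (4 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.264 with an estimated correlation), with Itgax at 2.79-fold, and 1 of 11 MHC class II genes was (8 adjusted over the list alone, camera adjusted p = 6.72e-07, adjusted p = 0.268 with an estimated correlation). Of 16 lipid handling genes, Olr1 and Plin2 were higher, at 2.69-fold and 1.60-fold (4 adjusted over the list alone, camera adjusted p = 0.00615, adjusted p = 0.476 with an estimated correlation). Of 14 goblet cell genes, Slc26a4 was higher at 10.1-fold (5 adjusted over the list alone, camera adjusted p = 0.000272, adjusted p = 0.476 with an estimated correlation).

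Of 17 immediate early genes, 8 were higher with IL-4 than with IL-4d2 (11 adjusted over the list alone, camera adjusted p = 4.94e-10, adjusted p = 0.264 with an estimated correlation), including Egr2 at 2.68-fold and Fos at 2.54-fold. Of 16 club cell genes, 4 were lower (5 adjusted over the list alone, camera adjusted p = 0.000272, adjusted p = 0.264 with an estimated correlation), among them Cldn10, 2.02-fold lower, and Hp, 1.90-fold lower. Ciliated cell genes were lower in 3 of 19 cases (6 adjusted over the list alone, camera adjusted p = 6.72e-07, adjusted p = 0.476 with an estimated correlation). None of the 3 calls was stable: with 1 array left out, Dnali1, Tubb4b and Tppp3 lost theirs in 5, 5 and 3 of 9 fits. The next probe set of Tubb4b gave 0.38. Bpgm, 2.03-fold lower, was 1 of 2 red blood cell genes of 4 that were lower (3 adjusted over the list alone, camera adjusted p = 0.000470, adjusted p = 0.264 with an estimated correlation). The other, Hbb-b2, lost its call in 5 of 9 fits with 1 array left out, and its next probe set gave 0.53. The heart muscle list was lower by a median of −1.39, with 0 of 14 genes called by limma, 11 at an unadjusted p under 0.05 and 7 adjusted over the list alone (camera adjusted p = 1.65e-05, adjusted p = 0.476 with an estimated correlation). Macrophage and monocyte genes were higher in 3 and lower in 2 of 20 cases (8 and 2 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.577 with an estimated correlation). Of 21 endothelial genes, 1 was lower (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00982, adjusted p = 0.577 with an estimated correlation). limma called 0 of 18 B cell, 0 of 22 interferon-gamma and Th1 and 0 of 22 cell cycle genes, with 2, 6 and 4 at an unadjusted p under 0.05 and 0, 0 and 0 adjusted over the list alone, and camera put these lists upward (adjusted p = 0.0289, 0.00884 and 0.0476, against adjusted p = 0.577, 0.577 and 0.643 with an estimated correlation). In the neutrophil list of 6, 2 were lower (2 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.102). Jchain, Ccl20 and Cxcl9 did not pass the test, with log2 differences of −0.17 ± 0.34, −0.21 ± 0.51 and −0.08 ± 0.50 between IL-4 and IL-4d2. The plasma cell list had a median of −0.14 and a mean of −0.03, where camera put it upward (adjusted p = 0.970), and limma called 0 of its 11 genes.

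**Figure D3:**
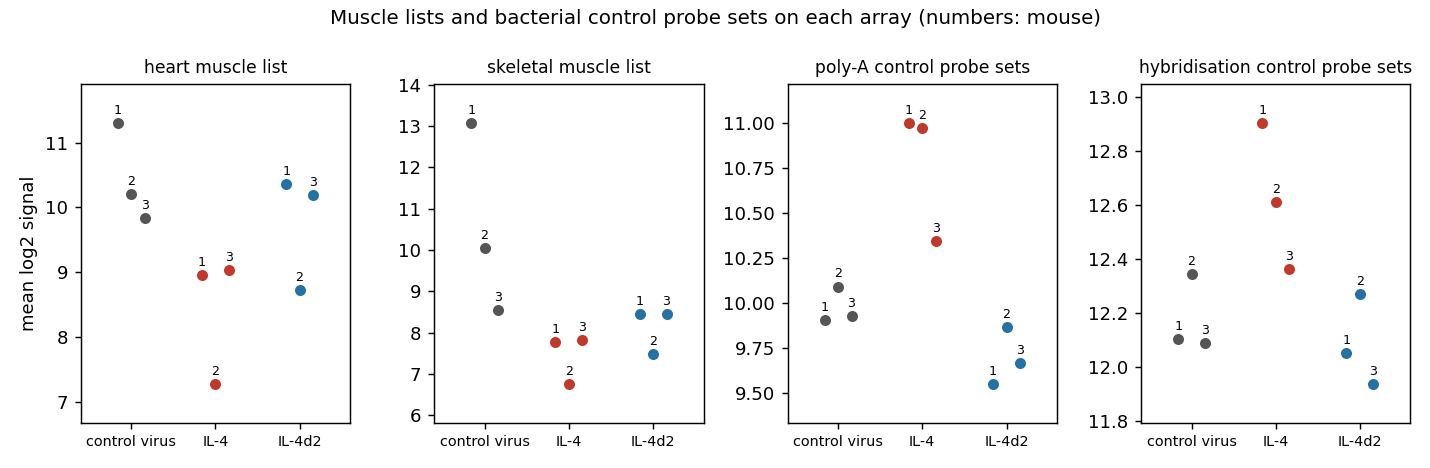
Mean log2 signal (vertical axes) of the heart muscle list, the skeletal muscle list, the poly-A control probe sets and the hybridisation control probe sets on each array; each point is 1 mouse with its number. The skeletal muscle mean of control mouse 1 was 13.1, and the poly-A controls were 1.74-fold brighter on IL-4 than on control arrays.

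For IL-4 against IL-4d2, limma called 416 probe sets, 217 higher with IL-4 and 199 lower, and 116 of them differed at least 2-fold. Groups did not overlap in 22.0% of the probe sets, where chance gives 10%. The count was 110 without IL-4d2 mouse 3, 186 or 190 without IL-4d2 mouse 1 or 2, 224 without IL-4 mouse 2, and 237 without control mouse 1 and IL-4 mouse 2. Without those 2 arrays, calls went from 8 to 6 for immediate early genes, 3 to 2 for dendritic cell, 3 to 1 for macrophage genes that were higher, 3 to 1 for ciliated cell and 2 to 1 for red blood cell genes. Scaling to the hybridisation or the poly-A controls moved the median of all genes by −0.52 or −1.04 and the calls to 89 higher and 11074 lower or to 33 higher and 22470 lower. The poly-A controls were 2.11-fold brighter on IL-4 than on IL-4d2 arrays (exact p = 0.1, the smallest possible). The 3'/5' ratio was 1.71 against 1.46 for Gapdh and 3.23 against 2.58 for Actb (exact p = 0.2 for each). The 18S ribosomal RNA signal was lower with IL-4 by a log2 difference of −0.57 (exact p = 0.2). The F test called 1850 probe sets among the 3 groups, 1053 without control mouse 1 and 1175 without control mouse 3. Of the 32 lists, camera called 23, 21 and 17 in the 3 comparisons at the preset correlation.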

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

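The test of a single scaling factor and that of the slopes between IL-4 mice with separate control arrays were chosen only after the result was seen. The difference between the cytokine forms was tested directly. The alternatively activated macrophage genes stood apart by that test, with a median log2 difference of 0.95 between IL-4 and IL-4d2, 0.73 above the control with IL-4 and −0.15 with IL-4d2. The arginine transporter Slc7a2 differed by 0.80 (limma adjusted p = 0.00161), at 0.36 with IL-4 and −0.44 with IL-4d2. The macrophage lectin Mgl2 differed by 1.07 (limma adjusted p = 0.00144), at 0.51 with IL-4 and −0.56 with IL-4d2. With 1 array left out, the IL-4d2 fall of Mgl2 was lost without any array but IL-4 mouse 1 (−0.59 to −0.53), and that of Slc7a2 without any array but IL-4 mice 1 and 2 (−0.49 to −0.40). Both stayed below 0 in each of these fits, and with all arrays the adjusted p was 0.0460 for Mgl2 and 0.0389 for Slc7a2.

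Bacterial control transcripts, which the comparisons between viruses do not use, were brighter on IL-4 than on control arrays, the poly-A controls by 0.80 and the hybridisation controls by 0.45 on the log2 scale (exact p = 0.1 for each, the smallest 3 arrays against 3 can give). A single scaling factor per array would move both sets alike, and they differed by 0.35, against a pooled SD of 0.13, which argues against it as the whole cause. A labelling difference of IL-4 mice 1 and 2 was also weighed as a cause of the calls: with separate control arrays for IL-4 mouse 3 and for the other 2, the slopes of mouse 3 on them were 0.918, 0.656 and 0.701 with control mouse 1, 2 or 3 set against mouse 3. No shared change would give 0 and labelling alone the ratio of the poly-A shifts, 0.449, 0.234 and 0.422, so that a part played by labelling stays open. A lower amount of lung RNA per array, for technical or biological reasons, stays open and may underlie part of the 0.80, and no biological explanation was tested.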

How the results depend on the processing

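The alternatives marked as added, namely 2 arrays left out and both scalings to control transcripts, were chosen only after the result was seen, and the cause was not tested for any change given here. Counts of called probe sets, 2546, 314 and 416 in the 3 comparisons (IL-4 and IL-4d2 against control virus, then IL-4 against IL-4d2) and 1850 by the F test, moved as follows. Without a filter, 244 differed between the forms and 1225 by F. Without a variance trend, 195 were called for IL-4d2, 165 between the forms and 1076 by F. Array weights gave 593 for IL-4d2, and 1 probe set per gene 149. A 2-fold minimum left 453, 110 and 116, and an adjusted p under 0.01 left 877, 134 and 114. Leaving out control mouse 1 and IL-4 mouse 2 (added) gave 1068, 200, 237 and 759. Scaling to the hybridisation controls (added) gave 7451 for IL-4, 11163 between the forms and 9510 by F, and to the poly-A controls (added) 18123, 519, 22503 and 22048. With 1 array left out, counts ran from 1313 to 2210, 156 to 417, 110 to 446 and 1053 to 1574, and shared calls from 143 to 353. The IL-4 count was 1313 without control mouse 1 and 1696 without control mouse 3. That of IL-4d2 was 187, 163 and 156 without IL-4d2 mice 1, 2 and 3, and 200 and 189 without control mice 1 and 3. That between the forms was 224 without IL-4 mouse 2, and 186, 190 and 110 without IL-4d2 mice 1, 2 and 3. By F it was 1053 and 1175 without control mice 1 and 3. Over the 3 groups, mouse numbers showed no clear pairing of arrays (r from −0.07 to 0.12 for the same number, −0.13 to 0.13 for other numbers). Between IL-4 and IL-4d2, r was 0.116, 0.102 and 0.0707 for the same number and −0.089 to −0.013 for other numbers. A pairing of those arrays stays open. With the number as a replicate block the counts were 2427, 312, 384 and 1723. Of 32 lists, camera called 23, 21 and 17, an estimated correlation 0, 0 and 1, and fry 15, 6 and 3. Of 247 results of named genes, 61 weakened without the 2 arrays. Of the named and called genes, 95 of 126, 28 of 49 and 28 of 53 kept their call in each of the 9 fits with 1 array left out. The next probe set turned the direction of Col1a1 for IL-4 (−0.15) and between the forms (−0.17), of Il4ra for IL-4d2 (−0.53) and between the forms (0.65), and between the forms of Stat6 (0.0095), Tubb4b (0.38), Hbb-b2 (0.53) and Cxcl9 (0.41). Uncalled genes also changed sign with 1 array left out: Cxcl9 (−0.37 to 0.24) and Jchain (−0.45 to 0.23) between the forms, and S100a9 (−0.22 to 0.45), Fbp1 (−0.22 to 0.075) and Arg1 (−0.70 to 0.0039) for IL-4d2. Of 89 uncalled genes picked by the rule and not named, 36 changed sign in 88 alternatives, to 0.73 at most in size, and 15 passed the threshold in some alternative. Uncalled lists changed direction in the test as well, given here by their medians. For IL-4d2 these were ciliated cell (−0.0077 with a pseudocount of 64, 0.014 without the 2 arrays, −0.079 to 0.014 with 1 array left out), goblet cell (−0.0031 without a filter, −0.052 without the 2 arrays, −0.21 to 0.12), neutrophil (0.26 without a filter, −0.20 to 0.25), club cell (0.019 with quantile normalization, −0.039 to 0.10), proinflammatory (0.14 without the 2 arrays, 0.12 to 0.29) and endothelial genes (0.0049 to 0.056). Between the forms these were plasma cell (−0.14 with quantile normalization, the replicate block and fry, −0.22 without the 2 arrays, −0.22 to 0.13), alveolar type 2 (−0.051 with quantile normalization, −0.0045 with fry, −0.077 without the 2 arrays, −0.077 to 0.11), type I interferon (0.061 without the 2 arrays, −0.074 to 0.061), lymphoid tissue (−0.14 to −0.018), alveolar type 1 (−0.18 to 0.011) and type 2 cytokine genes (−0.11 to 0.052). For IL-4 these were mast cell (0.24 with fry, 0.13 to 0.28) and red blood cell genes (−0.37 to −0.11).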

Other observations

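The gene groups in this part were chosen after the data were seen. The muscle spread, the comparison of muscle with lung cell lists and the gap between heat shock and immediate early genes were also chosen only after the result was seen, while the tests of quantile normalization, time of day, tissue handling and the splits of arrays were planned. Chaperones of the endoplasmic reticulum, which fold secreted proteins such as antibodies, rose with both cytokine forms. With IL-4, 12 of 17 rose (15 adjusted over the list alone, camera adjusted p = 0.0232 with an estimated correlation), and with IL-4d2 5 did (10 adjusted over the list alone, 0.0348). Sdf2l1 rose 2.20-fold and 1.69-fold, and Manf 1.97-fold and 1.67-fold. Detoxification genes, of which club cells express many, fell in 14 of 23 cases with IL-4 (16 adjusted over the list alone, 0.0232). They were lower with IL-4 than with IL-4d2 in 7 cases (13 adjusted over the list alone, 0.0390), and Pon1 was 4.02-fold lower with IL-4 than with control virus. C1qa, a chain of the complement component C1q that macrophages make, rose 2.05-fold and 2.17-fold. With IL-4d2 the C1qb call was lost without control mouse 3 (1.17) or IL-4d2 mouse 1 (1.12), 2 (1.01) or 3 (1.12), and the C1qc call without control mouse 1 (0.87) or 3 (0.81) or IL-4d2 mouse 1 (1.04), 2 (0.98) or 3 (0.91). Of the whole complement list of 12, 5 rose with IL-4 and 3 with IL-4d2 (5 and 4 adjusted over the list alone, 0.130 and 0.129). Chitinases and eosinophil-type ribonucleases rose in 7 of 8 cases with IL-4 (0.0232), among them Chia1 at 2.71-fold, and 6 of 8 were higher than with IL-4d2 (0.0211). Of 20 matrix-degrading proteases, 12 rose and 1 fell with IL-4 (12 and 3 adjusted over the list alone, 0.0881), with Mmp19 at 2.79-fold, and 6 were higher than with IL-4d2 (10 higher and 2 lower adjusted over the list alone, 0.103). Of 16 genes of resident alveolar macrophages, 5 rose and 4 fell with IL-4 (6 and 6 adjusted over the list alone, camera adjusted p = 0.697 at the preset correlation). Without control mouse 1 and IL-4 mouse 2, 10 endoplasmic reticulum chaperones, 3 complement genes, 4 chitinases and ribonucleases, 9 proteases and 3 alveolar macrophage genes rose with IL-4, 10 detoxification and 3 alveolar macrophage genes fell, 0 proteases fell and 1 detoxification gene rose. With IL-4d2 4 chaperones and 2 complement genes then rose, and against IL-4d2 5 chitinases and ribonucleases and 4 proteases were higher with IL-4, 7 detoxification genes were lower and 1 was higher.

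Of 22 heat shock genes, 16 rose with IL-4 and 15 with IL-4d2 (18 and 18 adjusted over the list alone, 16 and 14 without control mouse 1 and IL-4 mouse 2, camera adjusted p = 0.0232 and 0.0348 with an estimated correlation), while Egr1, Nr4a1, Fos and Cirbp fell with both. A single factor per array moves the 22 heat shock genes and the other 15 immediate early genes alike. Hspa1a and Hspa1b, members of both lists, counted here as heat shock genes only. The difference of the means of these groups changed by 1.47 with IL-4 (95% interval over mice 0.87 to 2.07) and 1.86 with IL-4d2 (1.24 to 2.48). A single factor cannot make such a gap. The groups were set against each other because they were seen to part, so the sign of the gap was fixed in advance. The intervals do not allow for that choice and are no independent test of a single factor. Quantile normalization, which kept at least 97.7% of the heat shock median, moved the median of all genes too little to test array scaling, which stays open in other forms. Time of day stays open, since the clock output genes had a median of −0.20 with IL-4d2 and −0.29 with IL-4, and collection times are not given in the sources used here. Handling between death and lysis may also have differed between groups. The heat shock and immediate early means of the 9 arrays correlated within groups at r = 0.105 (permutation p = 0.811). Hspa1a and Hspa1b counted in both of these means, which can push r upward. A negative r was written beforehand as the mark of handling. Yet the planned list of immediate early genes, meant to read tissue handling, holds Hspa1a and Hspa1b beside Fos and Egr1. The sign that handling would give is thus not established, and r cannot decide. Handling therefore stays open, as does a stress response of the lung to the cytokine forms, which was not tested.

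Muscle genes were lower on IL-4 arrays and highest on the array of control mouse 1. Dilution by infiltrating cells would lower all lung cell genes as far as the heart list. The heart mean differed by −2.03 (95% interval over mice −4.04 to −0.015). Without control mouse 1 and IL-4 mouse 2 it differed by −1.02 (−1.85 to −0.20). The endothelial, alveolar type 1, alveolar type 2 and club cell means differed by −0.15, −0.19, 0.24 and −0.35. Their lowest 95% bound over mice was −0.97 (−0.79 without those arrays). That bound lies above the heart difference but inside its interval, so the comparison cannot decide. Muscle varied so much between mice that the heart minus endothelial difference, −1.88, had an interval of −4.03 to 0.27 (−0.82, −1.87 to 0.23, without those arrays). Dilution as part or the whole of the cause stays open. Muscle carried over at dissection stays open too: the within-group SD of the heart and skeletal lists stood at percentile 100 of 1000 random lists, but genes of a tissue vary together whatever the cause, and the skeletal list was chosen after its spread was seen. Heart muscle in the walls of pulmonary veins is a biological source that was not tested.

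For each comparison of 3 arrays against 3, the 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 2546, 314 and 416 calls, and the highest other split gave 0, 0 and 1, so 1 of 10 splits gave as many in each. For the 3 groups together, 1 of 100 splits, the real one itself, gave as many as the real 1850, with 369 as the highest other. That is the smallest share that 100 splits can give, and it argues against chance without excluding it. The splits cannot tell the viruses from anything else that differed between the groups.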
